A study of Rattus norvegicus with 8 samples.

How the data were processed

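Total RNA from primary rat hippocampal neurons was measured on 8 one-colour Agilent arrays, 4 from neurons that received a scrambled control shRNA and 4 from neurons that received an shRNA against rat Sirt6. Groups and replicate numbers were taken from the labels. The labels do not say whether the 4 samples of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

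The spot intensity values are those of Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes and per the file headers, after background subtraction and spatial and multiplicative detrending by that software, with no normalization between arrays. The deposited files also hold, per the file headers, the raw mean intensity of each spot, the median intensity of its local background, and flags for outlier spots, saturation and signal well above background. A separate deposited table holds the authors' log2 values. Set against the scanner values of the same array, each of its columns equalled the log2 processed signal minus 1 constant, with an SD of the difference of at most 0.0029, and its 75th percentile lay at 0. Its column medians ran from -3.71 to -3.60. Every value column of that table was mapped to a sample by name.

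Outlier spots were left out, as were control spots. Spots of 1 probe were averaged on the log2 scale, and each array's 75th percentile over its 45598 non-control probes was subtracted. A probe was kept if it was well above background on at least 4 of the 8 arrays, whatever their group, which left 28620 probes. Probes were named through their accessions in a RefSeq gene table of the assembly GRCr8, used for names only: 21109 probes matched by their systematic name, 2615 by another RefSeq accession, 5164 by symbol and 353 by an older symbol. Another 16336 probes kept the name in the file, and 21 had none. Where several kept probes shared a gene, the brightest on average over the 8 arrays stood for it, giving 22587 genes.

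Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 33 lists, with camera at an estimated correlation and fry beside it. The lists, holding 1030 distinct genes of which 25 stood in more than 1 list, were written before the data were examined, as were the main design and most of the alternative settings. The genes named were fixed by rule at that point too. The rule took Sirt6 first. It then took, among called genes with a gene symbol whose groups did not overlap and whose probe was well above background on all 4 arrays of the higher group, the 12 largest rises and the 12 largest falls. Last, it allowed for each list described up to 4 called members of largest absolute log2 fold change, or the 2 of smallest p where fewer than 2 were called. The mean deviation of a list's members from their 8-array means was also compared between the groups with a two-sided exact permutation test, for which 0.0286 is the smallest p that 4 arrays against 4 can give. That comparison was added after the data had been seen. One of the 33 lists and 1 gene are tested but not reported here.

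Where a probe was not well above background on any array of the dimmer group, its fold is a lower bound. It sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background, on normalized log2 values. The same raised signals give the second fold named for Gpx3, Shisa3 and Mfrp, which were well above background on 1 array of that group.

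The fit was tested on 1 draw of simulated data for this comparison over the 22587 genes, 200 of them changed. It recovered 42.6% of genes changed by 0.3 on the log2 scale, 66.7% at 0.6 and 84.8% at 1. Among its calls 7.19% were unchanged genes, above the nominal rate. The simulation changed a far smaller share of genes than the 30.4% called in the data, and its noise was independent between genes. Its rates therefore do not carry over to the real calls. The number of arrays limits the precision.

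Alternatives covered the background correction (normexp with an offset of 50), quantile normalization, median centring, the authors' log2 values, the filter on dim probes, the mean of a gene's probes, all kept probes, eBayes with trend and robust options, array weights, the replicate number as a block, and the omission of each array in turn. Scaling on the E1A spike-in probes and adding 16 to each signal before log2 were chosen after seeing the data. All 8 arrays lay on 1 slide, per the file headers, so a block for slide or scan was not run. The scrambled arrays filled row 1 of the slide and the Sirt6 shRNA arrays row 2, so slide row and group cannot be told apart.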

Results

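The data are gene expression profiles of hippocampal neurons prepared from newborn Wistar rats, collected to ask what SIRT6, a NAD-dependent deacetylase of the sirtuin family, does in the shaping of neurons. Neurons were infected with lentiviral vectors on day 3 in culture, at a multiplicity of infection of 6, and RNA was taken 7 days later, at day 10. One group of 4 samples carried a scrambled shRNA and the other group of 4 an shRNA against rat Sirt6. Each array held 45598 non-control probes, of which 60.4% to 65.3% were well above background, and its median processed signal was between 24.1 and 27.5. Log2 profiles correlated at r = 0.9954 to 0.9975 within a group and at 0.9912 to 0.9935 between groups, across genes, which are not independent replicates.

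Sirt6 itself was lower in every array that carried its shRNA. Its processed signal was 1336 ± 13.2 (SD, n = 4) with the scrambled shRNA and 476.6 ± 20.3 (SD, n = 4) with the Sirt6 shRNA. On the normalized scale it fell by 1.53 ± 0.040 (SE) in log2, which left 34.6% of the control level (limma adjusted p = 5.55e-06), and it ranked 1 of 22587 genes by p. The array carries 1 probe for Sirt6 (A_64_P089931), which the files place on chromosome 7 at 9560618 to 9560677 in build rn4. Which exon or UTR that span lies in was not analysed here. Only 1 shRNA against Sirt6 was compared with 1 scrambled shRNA, so the comparison holds any other effect of either vector.

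**Figure D1:**
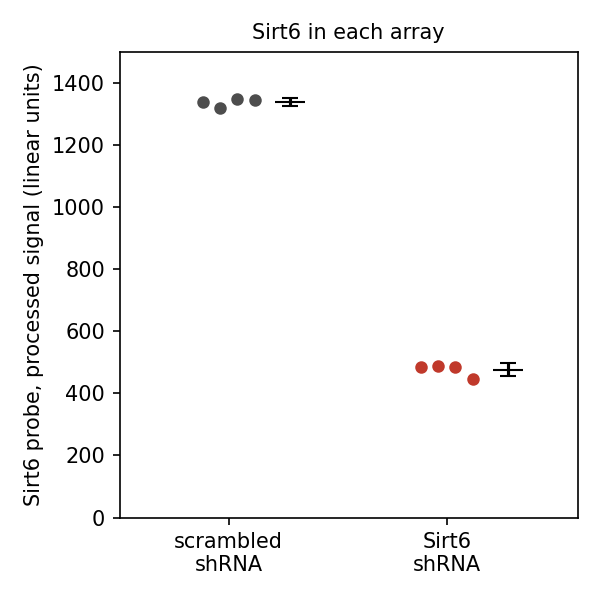
Processed signal of the Sirt6 probe in linear units (vertical axis, from 0) for the 4 scrambled shRNA and 4 Sirt6 shRNA arrays; points are arrays, and the bar with its whiskers is the group mean ± SD. The Sirt6 shRNA arrays lie between 446.3 and 489.3 and the scrambled arrays between 1318 and 1347.

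The comparison of all genes asked which transcripts differ when Sirt6 is lowered. Cd36, a fatty acid transporter, and the contractile genes Tagln, Tpm2 and Myl9 were among the largest rises, and Npas4, Fosb and Arc, which neuronal activity induces, were among the largest falls. In total 3523 genes were higher and 3351 lower with the Sirt6 shRNA, 30.4% of those tested. Most changes were small: the median absolute log2 fold change of called genes was 0.30, and 1002 of them, or 14.6%, reached 1.5-fold, 441 upward and 561 downward. A 2-fold change was reached by 84 higher and 126 lower genes. The 4 arrays of one group all lay above the 4 of the other for 33.4% of the genes tested, where chance alone gives 2.86%. The share of higher genes among the called depended on the scaling: it was 51.3% here, 35.2% after median centring and 64.2% after scaling on spike-ins, a choice made after seeing the data.

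Among the largest rises, Cd36, a fatty acid transporter and scavenger receptor, rose 5.04-fold (log2 2.33 ± 0.078 SE, n = 4 per group). Olah, a thioesterase that ends fatty acid chain growth, rose at least 4.62-fold, and Cd36l1, a Cd36-like gene, at least 5.16-fold, since neither was well above background in any scrambled array. A probe may not tell Cd36 and Cd36l1 apart. Several of the others encode parts of the contractile apparatus. Tagln, an actin-binding protein of smooth muscle, rose 4.40-fold (log2 2.14 ± 0.11), the tropomyosin gene Tpm2 4.28-fold, Pdlim3, which binds alpha-actinin, 3.67-fold, and Myl9, a regulatory light chain of myosin, 3.12-fold. The other 2 probes of Tpm2 gave log2 changes of 1.33 and 1.91. Slc5a7, the high-affinity choline transporter, rose 3.05-fold and Insc, an adaptor in spindle orientation, 2.86-fold. RT1-T24-3, of the rat major histocompatibility complex, rose 3.12-fold on its brightest probe but its other probe gave a log2 change of 0.18, and this family has near-identical members. Cfap107 rose at least 2.83-fold and the methyltransferase gene Ntmt2 at least 2.33-fold (adjusted p = 0.0175, the highest among these 12).

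The largest falls included 3 genes that neuronal activity induces. Npas4, an activity-dependent transcription factor, fell at least 4.48-fold and was not well above background in any Sirt6 shRNA array. Fosb, of the Fos family, was 5.20-fold lower (log2 -2.38 ± 0.11 SE, n = 4 per group), and Arc, which acts on glutamate receptor uptake at synapses, was 3.79-fold lower (log2 -1.92 ± 0.12). Gja5, a gap junction protein, was 3.98-fold lower and its other probe gave a log2 change of -2.02. Fmod, a collagen-binding proteoglycan, was 3.92-fold lower, and Serpina3n, a secreted protease inhibitor, 3.88-fold lower. Gpx3, the extracellular glutathione peroxidase, was 4.50-fold lower and Shisa3 4.48-fold lower, each well above background in only 1 of the 4 Sirt6 shRNA arrays, and 4.50-fold and 4.29-fold with the signals of these arrays raised to the background limit. Mfrp, above background in 1 of these 4 arrays as well, was 4.88-fold lower as fitted and 3.39-fold with raised signals (adjusted p = 0.0222), a call lost without scrambled replicate 3 and without Sirt6 shRNA replicate 3 (adjusted p = 0.0524 in each case). Tmem82 was 3.83-fold lower, with a log2 change of -1.01 on its other probe. The dipeptidase gene Dpep1 fell at least 2.26-fold and Kng2, a kininogen with close paralogs, at least 2.56-fold.

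**Figure D2:**
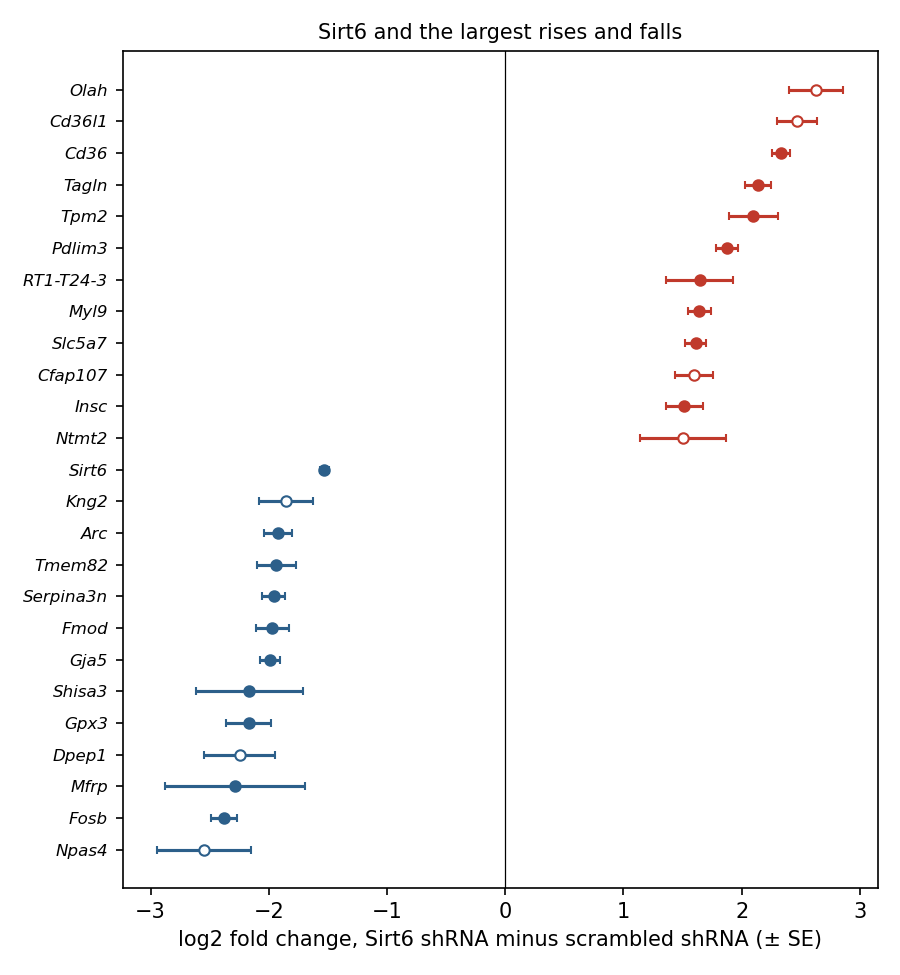
Log2 fold change (horizontal axis, Sirt6 shRNA minus scrambled shRNA) with its standard error for Sirt6 and the 12 largest rises and 12 largest falls; open circles mark genes not well above background in any array of the dimmer group, plotted at the fitted value and not at the bound given in the text. The fitted values run from -2.55 for Npas4 to 2.63 for Olah.

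Activity-regulated genes fell as a group: 23 of the 38 measured were lower and 2 higher, or 25 and 2 adjusted over the list alone, with a median log2 fold change of -0.33. Besides Npas4, Fosb and Arc, the nuclear receptor gene Nr4a2 was lower (log2 -1.12 ± 0.055 SE), though of its 2 other probes 1 gave -1.03 and the other, dimmer, 0.035. The camera adjusted p was 3.23e-09, and the adjusted p was 0.244 with an estimated correlation. The mean over the list was lower in all 4 Sirt6 shRNA arrays than in any scrambled array, with a difference of -0.512 in log2 (exact permutation p = 0.0286).

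Astrocyte markers also fell: 21 of 29 were lower and 1 was higher, or 24 and 1 adjusted over the list alone, with a median of -0.33 (camera adjusted p = 2.84e-10; adjusted p = 0.244 with an estimated correlation of 0.161). S100b, a calcium-binding protein, changed by -1.42 ± 0.078 in log2, Gfap, the intermediate filament of astrocytes, by -0.71 ± 0.069, and the gap junction gene Gja1 by -0.63 ± 0.062. Gjb6, another gap junction gene of astrocytes, went the other way and rose by 1.15 ± 0.11. List means did not overlap between the groups and differed by -0.324 (exact permutation p = 0.0286).

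NF-kB targets were lower for 19 of 27 members and higher for 0, or 21 and 0 adjusted over the list alone (camera adjusted p = 1.52e-08; adjusted p = 0.244 with an estimated correlation). Their array means did not overlap between the groups (difference -0.371, exact permutation p = 0.0286). The chemokine gene Ccl2 changed by -1.29 ± 0.078 in log2 and the adaptor gene Traf1, well above background in 2 of the 4 Sirt6 shRNA arrays, by -0.67 ± 0.12. Cxcl10 changed by -0.76 ± 0.21 and Tnf by -0.72 ± 0.18, and for both the groups overlapped and the call was lost in 5 of the 8 omissions of 1 array (highest adjusted p = 0.0716 for Cxcl10 and 0.0573 for Tnf). Genes of the interferon response were lower for 13 of 34 and higher for 0, or 14 and 0 adjusted over the list alone (camera adjusted p = 5.59e-05; adjusted p = 0.878 with an estimated correlation of 0.608), among them Ifit3 with -1.31 ± 0.26 and Irf7 with -0.95 ± 0.19. The array means of this list overlapped between the groups (exact permutation p = 0.0571). Microglia and macrophage markers were lower for 6 of 27 and higher for 0, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.000362; adjusted p = 0.878 with an estimated correlation). The share of these markers called was below the 30.4% called over all genes. Gpnmb changed by -1.31 ± 0.066 and Tmem119 by -0.89 ± 0.18. Array means of the microglia list overlapped between the groups (difference -0.423, exact permutation p = 0.114), with Sirt6 shRNA replicate 2 at 0.325 and the other Sirt6 shRNA arrays between -0.505 and -0.292.

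In metabolism, fatty acid and lipid synthesis genes were lower for 12 of 21 and higher for 2, with the same counts adjusted over the list alone (camera adjusted p = 3.18e-05; adjusted p = 0.304 with an estimated correlation). Thrsp, a regulator of lipogenesis, changed by -1.62 ± 0.23 in log2, the desaturase genes Scd and Scd2 by -1.06 ± 0.13 and -0.73 ± 0.047, and Gpam, which starts glycerolipid synthesis, by -0.82 ± 0.070. The antioxidant response list had 13 of 31 members lower and 2 higher, or 15 and 3 adjusted over the list alone (camera adjusted p = 0.00119; adjusted p = 0.805 with an estimated correlation), with Sod3 at -0.92 ± 0.063, the metallothionein gene Mt1 at -0.82 ± 0.077 and Hmox1, haem oxygenase, at -0.80 ± 0.077. Of the unfolded protein and amino acid stress list 16 of 37 were lower and 6 higher, or 17 and 9 adjusted over the list alone (camera adjusted p = 0.0149; adjusted p = 0.805 with an estimated correlation). Sdf2l1 was at -0.85 ± 0.069 and Nupr1, a stress-induced regulator, at 0.79 ± 0.083. Insulin and IGF signalling genes were lower for 13 of 33 and higher for 3, or 14 and 4 adjusted over the list alone (camera adjusted p = 0.0426; adjusted p = 0.805 with an estimated correlation), with the binding proteins Igfbp5 at -0.65 ± 0.092 and Igfbp6 at 0.56 ± 0.049. This call was lost without scrambled replicate 1 (adjusted p = 0.0930) and without Sirt6 shRNA replicate 2 (0.104). Mitochondrial respiratory chain genes were lower for 8 of 44 and higher for 1, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0456; adjusted p = 0.878 with an estimated correlation), with Ndufa10 at -0.39 ± 0.089 and Sdhc at -0.33 ± 0.049. That call was lost without scrambled replicate 1 (adjusted p = 0.101) or 2 (0.129) and without Sirt6 shRNA replicate 2 (0.104) or 3 (0.144). A smaller share of the mitochondrial list was called than the 30.4% called over all genes. Array means of the mitochondrial list overlapped between the groups (difference -0.0625, exact permutation p = 0.0857), while those of the fatty acid (-0.377), antioxidant (-0.202), unfolded protein (-0.115) and insulin (-0.0939) lists did not (exact permutation p = 0.0286 for each).

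The lists called higher were DNA repair, proliferating cell genes and presynaptic proteins, each with a share of called members near the 30.4% of all genes. Array means of the first 2 did not overlap between the groups (differences 0.109 and 0.285, exact permutation p = 0.0286 for each). DNA repair genes were higher for 10 of 37 and lower for 1, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.0426; adjusted p = 0.244 with an estimated correlation of -0.0174), with Nhej1, of non-homologous end joining, at 0.74 ± 0.051 and Mdc1 at 0.35 ± 0.035. That estimate lies below the preset 0.01, so a higher correlation is not why this list no longer passed. The call was lost without scrambled replicate 1 (adjusted p = 0.0798) and without Sirt6 shRNA replicate 1 (0.0521). Proliferating cell genes were higher for 9 of 32 and lower for 1, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.0149; adjusted p = 0.878 with an estimated correlation of 0.573). Nes, the intermediate filament of neural progenitors, was at 0.63 ± 0.049 and Nusap1 at 0.62 ± 0.16. The list call was lost without scrambled replicate 1 (adjusted p = 0.0652) and without Sirt6 shRNA replicate 2 (0.0572), the array with the highest list mean at 0.499, whose omission lowers the difference in list means from 0.285 to 0.166. Without scrambled replicate 1 Nusap1 was no longer called (adjusted p = 0.0568). Presynaptic proteins were higher for 10 of 42 and lower for 2, with the same counts adjusted over the list alone (camera adjusted p = 0.0404; adjusted p = 0.878 with an estimated correlation), with the vesicular glutamate transporter gene Slc17a6 at 0.40 ± 0.049 and Stx1a at 0.39 ± 0.045. Array means of this list overlapped between the groups (exact permutation p = 0.0571). The call was lost without scrambled replicate 2 (adjusted p = 0.0613) or 3 (0.0654) and without Sirt6 shRNA replicate 1 (0.0553) or 4 (0.0643).

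**Figure D3:**
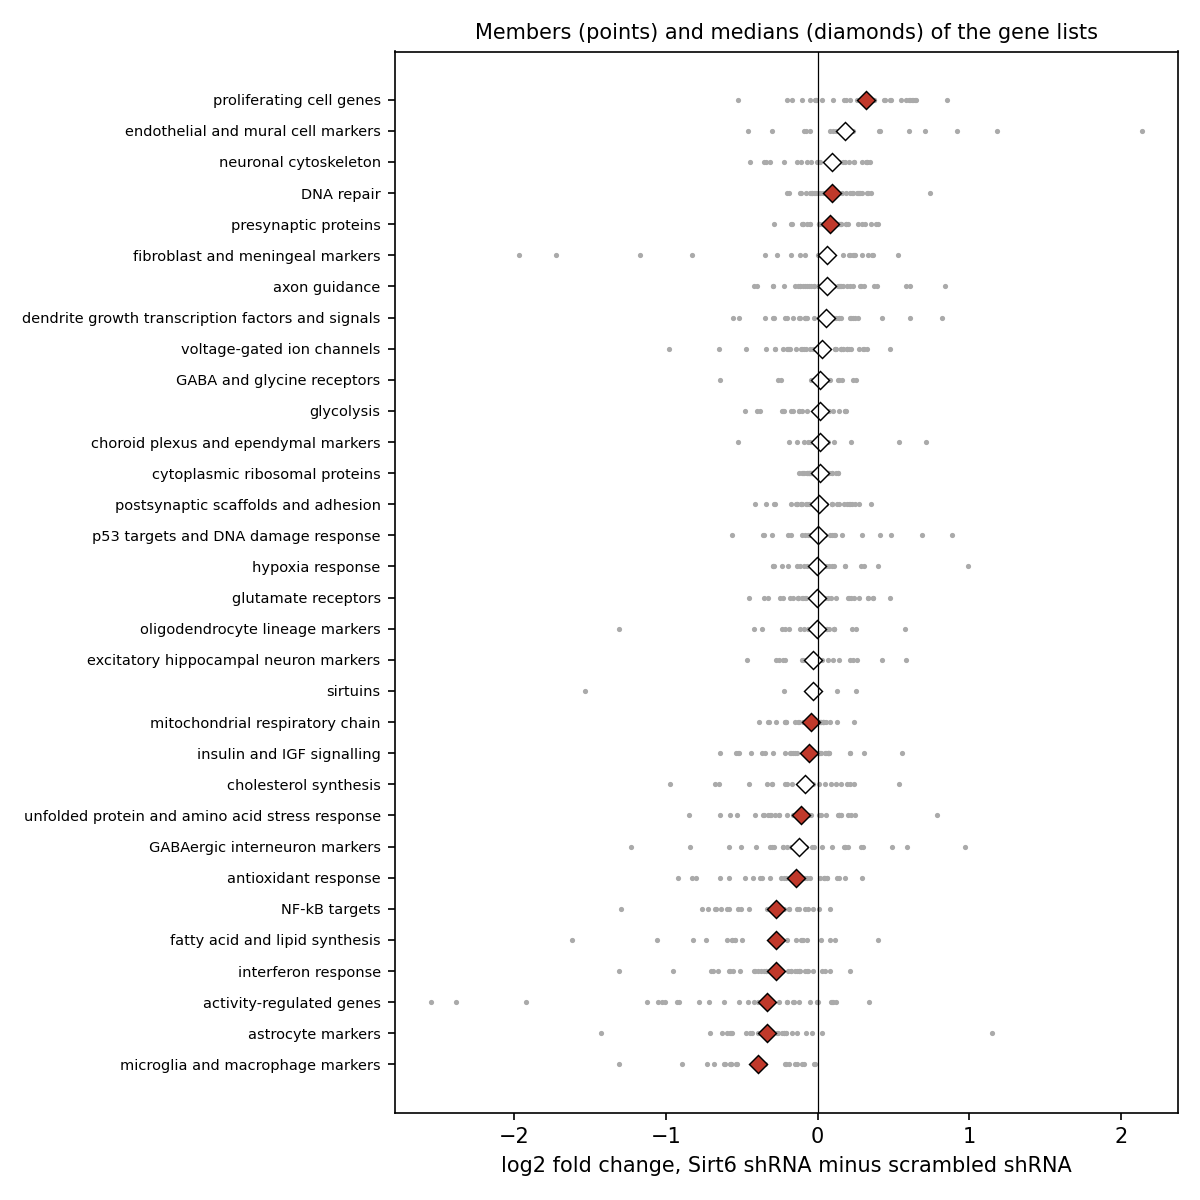
Log2 fold change (horizontal axis, Sirt6 shRNA minus scrambled shRNA) of the measured members (points) and the median (diamond) of 32 of the 33 gene lists; filled diamonds mark lists past camera's threshold at the preset correlation. With an estimated correlation 0 lists passed.

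**Figure D4:**
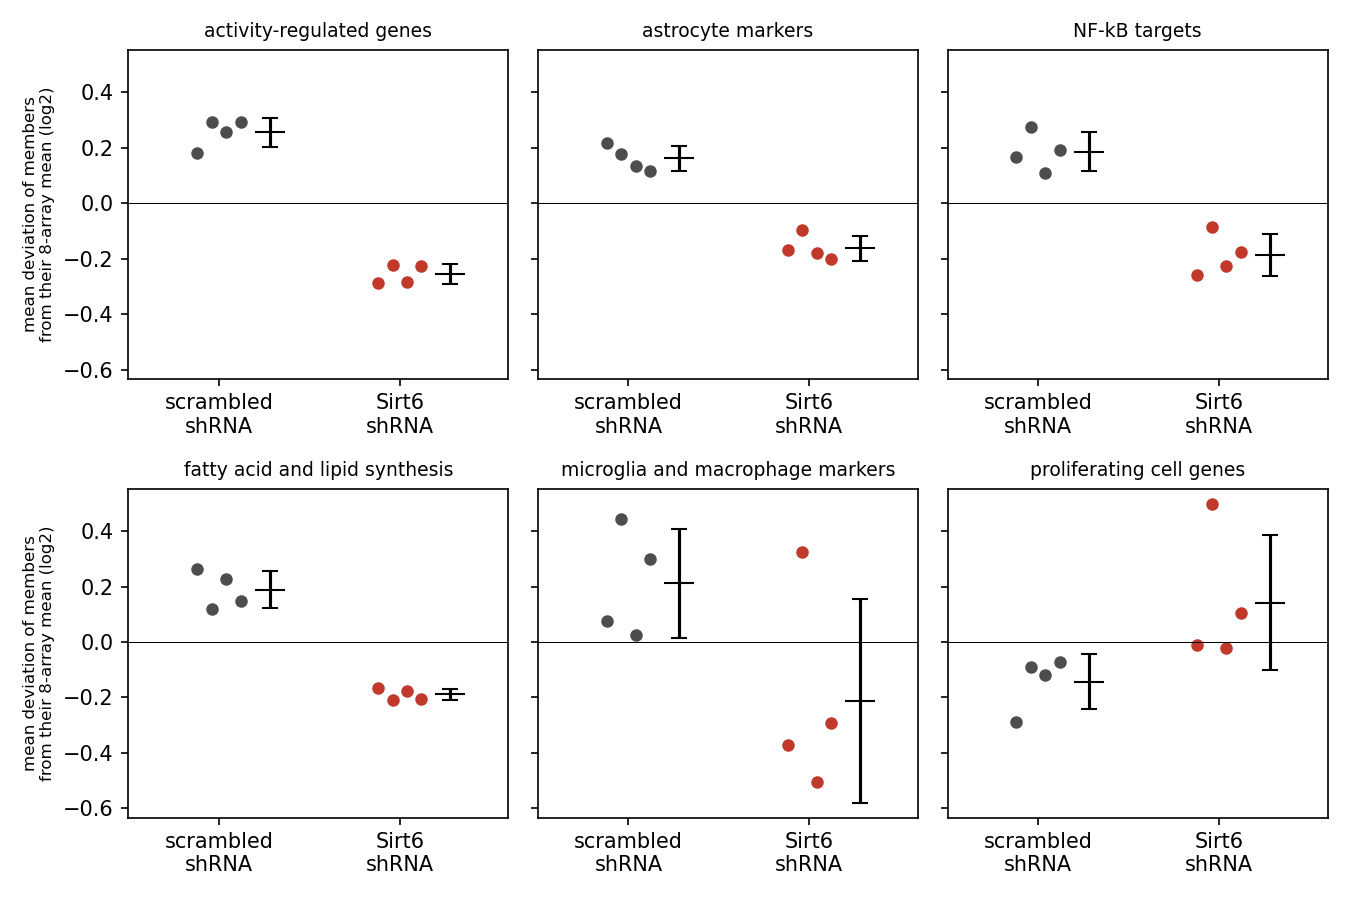
Mean deviation of a list's members from their 8-array means (vertical axis, log2) in each array for 6 lists; points are arrays, and the bar with its whiskers is the group mean ± SD. Activity-regulated genes separate the groups, whereas the microglia list overlaps, with Sirt6 shRNA replicate 2 at 0.325.

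The other 20 lists did not pass camera. Among markers of other cells, the endothelial and mural list had 6 of 16 members higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.0785), with Tagln, Abcc9 at 1.18 ± 0.27 (well above background in 2 of the 4 scrambled arrays) and the smooth muscle myosin gene Myh11 at 0.92 ± 0.089. Fibroblast and meningeal markers had 8 of 24 higher and 5 lower, or 10 and 6 adjusted over the list alone (camera adjusted p = 0.939), with Fmod and Mgp at -1.97 and -1.72 and Slc6a13 at 0.53. Oligodendrocyte lineage markers had 2 of 21 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.664), with Mbp, myelin basic protein, at -1.31 ± 0.11 on its brightest probe and at 0.028 on its other. Choroid plexus and ependymal markers had 2 of 13 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.939), with Enkur at 0.71. Of the neuron classes, GABAergic interneuron markers had 7 of 29 higher and 11 lower, or 8 and 12 adjusted over the list alone (camera adjusted p = 0.124), with Cort at -1.23 ± 0.080 and Pvalb, parvalbumin, at -0.84 ± 0.077. Excitatory hippocampal neuron markers had 5 of 20 higher and 5 lower, the same adjusted over the list alone (camera adjusted p = 0.939), with Wfs1 at 0.58.

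For the question of neuronal shape, members of the lists moved both ways. Genes of axon guidance were higher for 12 of 42 and lower for 5, or 13 and 5 adjusted over the list alone (camera adjusted p = 0.334, fry adjusted p = 0.0148; array means 0.0732 higher without overlap, exact permutation p = 0.0286), with Sema5a at 0.84 ± 0.087 and the netrin receptor gene Dcc at 0.61 ± 0.14 (0.26 on its other probe). Neuronal cytoskeleton genes were higher for 9 of 31 and lower for 5, or 11 and 5 adjusted over the list alone (camera adjusted p = 0.304), with Dclk1 at -0.44 on its brightest probe and at -0.19 and 0.023 on 2 dimmer ones. Dendrite growth transcription factors and signals were higher for 8 of 37 and lower for 6, or 11 and 7 adjusted over the list alone (camera adjusted p = 0.885), with the neurotrophin gene Ntf3 at 0.82 ± 0.10, Neurod1 at 0.61 ± 0.082 and Ntrk2, the receptor of BDNF, at -0.56 ± 0.045 on its brightest probe and between -0.62 and 0.13 on its 5 others. Postsynaptic scaffolds and adhesion genes were higher for 8 of 35 and lower for 5, the same adjusted over the list alone (camera adjusted p = 0.992), with Homer3 at -0.41. Glutamate receptors were higher for 7 of 34 and lower for 5, or 9 and 6 adjusted over the list alone (camera adjusted p = 0.992). GABA and glycine receptors were higher for 2 of 19 and lower for 3, the same adjusted over the list alone (camera adjusted p = 0.939), with Gabrg1 at -0.64. Voltage-gated ion channels were higher for 9 of 47 and lower for 9, or 10 and 9 adjusted over the list alone (camera adjusted p = 0.992), with the potassium channel gene Kcna1 at -0.98 ± 0.044.

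Among the remaining lists, cholesterol synthesis had 3 of 24 higher and 10 lower, or 3 and 11 adjusted over the list alone (camera adjusted p = 0.0785), with Insig1 at -0.97 ± 0.058. Glycolysis had 4 of 26 higher and 9 lower, or 4 and 10 adjusted over the list alone (camera adjusted p = 0.334), with the lactate transporter gene Slc16a1 at -0.48. The hypoxia response had 6 of 22 higher and 4 lower, or 7 and 5 adjusted over the list alone (camera adjusted p = 0.939), with Car12 at 0.99 ± 0.083. For p53 targets and the DNA damage response the counts were 3 of 31 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.939), with Perp at 0.69. Of the 7 sirtuins, Sirt6 and Sirt2 (-0.22 ± 0.042) were lower and Sirt1 was higher (0.26 ± 0.058), or 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.434). Cytoplasmic ribosomal proteins had 0 of 55 higher and 0 lower (camera adjusted p = 0.992), and Rps7 was at 0.12 ± 0.042 (adjusted p = 0.0658). By array means the endothelial (0.371), fibroblast (-0.14), cholesterol (-0.127) and sirtuin (-0.209) lists, too, did not overlap between the groups (exact permutation p = 0.0286 for each), and fry passed the endothelial (adjusted p = 0.00242), cholesterol (0.0247), GABAergic (0.0247) and sirtuin (2.66e-05) lists. The sirtuin list holds Sirt6 itself. The sign of the median, the mean or the camera direction differed for the glycolysis, p53, excitatory neuron, fibroblast, hypoxia, voltage-gated channel and glutamate receptor lists.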

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

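Of 306 groups of 4 arrays examined (104 genes named in the text, 7 measures of array quality and 42 gene lists, in each group), 23 held an array that stood far from its 3 companions relative to the group's range, where chance gives about 1 in 20, or 15.3. No explanation was tested for these.

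Among the genes, on the normalized log2 scale, Mfrp in scrambled replicate 3 was at -2.69 against at most -3.93 in the other 3, and Shisa3 in scrambled replicate 2 was at -1.82 against -3.90 to -3.64. Irf7 in scrambled replicate 3 was at 2.17 against 2.75 to 2.83, Cd46 there at -2.26 against -2.59 to -2.54, Myh11 there at -2.31 against -2.57 to -2.54 and Mdc1 there at 0.588 against 0.535 to 0.542. Egr1 in scrambled replicate 1 was at 0.694 against 0.945 to 0.989, and Per2 there at -0.572 against -0.335 to -0.296. Scrambled replicate 4 was apart for Cd36l1, at -6.82 against -6.22 to -6.16 (not well above background in any of the 4), and for Dclk1, at 3.62 against 3.71, and scrambled replicate 2 for Igfbp6, at -2.85 against -2.98 to -2.97. In the Sirt6 shRNA group, Ntmt2 in replicate 3 was at -4.27 against -5.01 to -4.96 and Ciart in replicate 1 at -3.17 against -2.94 to -2.91. Sirt6 shRNA replicate 2 was apart for Sod3, at 1.03 against 0.762 to 0.798, and for Tmem119, at -1.49 against -2.22 to -2.11.

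In array quality, scrambled replicate 1 had 0.64% of its spots marked as outliers, against 0.465% to 0.48% in the other scrambled arrays, and a mean negative control signal of 1.81 against 1.23 to 1.32. Of the list means, expressed as the deviation from the 8-array mean in log2, Sirt6 shRNA replicate 2 was apart for complement genes, at -0.0217 against -0.319 to -0.279, and for dendrite growth factors and signals, at -0.0108 against 0.0214 to 0.0275. DNA repair in Sirt6 shRNA replicate 4 was at 0.037 against 0.0593 to 0.0611, late-response activity genes there at -0.0196 against -0.097 to -0.0933, and oligodendrocyte markers in Sirt6 shRNA replicate 3 at -0.0772 against -0.0203 to -0.0154. GABAergic interneuron markers in scrambled replicate 1 were at 0.126 against 0.00173 to 0.0212.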

How the results depend on the processing

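The comparison with other splits, and the spike-in scaling and the addition of 16 to each signal, were chosen after the data had been seen. The fall of Sirt6 was called in all 21 other settings, with log2 fold changes from -1.57 to -1.40. Genes higher were 2000 after median centring and 2096 with spike-in scaling, and genes lower 1170 with spike-in scaling, against 3523 and 3351. Of those 2000 and 2096 genes, 1998 and 1973 were also among the 3523, and 1167 of the 1170 among the 3351. A single factor per array sets these differences. Omission of 1 array left 2631 to 3278 genes higher and 2683 to 3310 lower. The replicate block gave 3202 higher and 3222 lower, of which 2867 and 2876 were also called in the main analysis. With the block the DNA repair and the insulin and IGF signalling lists were no longer called. Arrays of the same number deviated together with r = 0.0639, 0.16, 0.133 and 0.0326, and arrays of different number with r from -0.221 to 0.12. The replicate number is also the slide column in both groups. These weak correlations do not settle whether the numbers pair the samples. Gene lists called higher, 3 in the main analysis, were 0 without a filter on dim probes, 1 with the mean of a gene's probes, 1 with array weights, and 1 to 3 when 1 array was omitted (1 without scrambled replicate 1). Lists called lower, 10 in the main analysis, were 8 to 11 when 1 array was omitted and at most 13 in the other settings. With an estimated correlation 0 lists were higher and 0 lower (lowest adjusted p = 0.244), and fry called 4 higher and 10 lower. The cause was not tested. The calls of astrocyte markers, activity-regulated genes, NF-kB targets, fatty acid synthesis, antioxidant and unfolded protein lists held in 22 of 23 alternatives, all but the estimated correlation, and those of the interferon and microglia lists in 21, failing with fry too (adjusted p = 0.0565 and 0.132), as did the proliferating and mitochondrial lists (0.151 and 0.138). Proliferating cell genes held in 17, DNA repair and presynaptic proteins in 14 each, insulin and IGF signalling in 13 and the mitochondrial list in 10. Named genes other than Sirt6 kept their call or lack of one in 2927 comparisons, lost a call in 117 and gained one in 8, with 0 reversals. Probes near the background limit small signals: the mean dark-corner signal was 1.73 to 2.46 in the Sirt6 shRNA arrays and 1.27 to 1.74 in the scrambled ones, and 7 spike-in probes differed by -0.11 to -0.0386 in log2 between the groups.

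Among the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many as 6874 called genes, and the highest other gave 1. That is a share of 0.0286, the smallest that 35 splits can give. Every other split mixes the groups, so a real difference adds to its within-group spread and can lower its count. The splits alone therefore do not exclude chance for that count. For called lists, too, only 1 split, the real one, reached 13, but the highest other gave 12. Camera at its preset correlation of 0.01 can call lists whose members vary together. Splits with 3 arrays of a group on 1 side also keep part of the real difference (7 to 12 lists, with 2 arrays 0 to 12). Neither was tested. Among the 13 called lists the estimated correlation ran from -0.0174 for DNA repair to 0.814 for microglia markers. List by list, the number of splits with a camera p as small as the real one, itself included, was 1 for astrocyte markers, NF-kB targets and DNA repair, 2 for activity-regulated genes and fatty acid synthesis, and 4 for the antioxidant, unfolded protein and insulin lists. It was 10 for the interferon response, 12 for presynaptic proteins, 14 for the mitochondrial list, 15 for microglia markers and 20 for proliferating cell genes. Even for the 3 lists at 1, camera gave an unadjusted p under 0.05 in other splits (19 for NF-kB targets, 16 for astrocyte markers and 7 for DNA repair). Array means gave the smallest p possible, 0.0286, for these 3 and for the activity, fatty acid, antioxidant, unfolded protein, insulin and proliferating lists, and 0.0571 to 0.114 for the other 4. Neither measure was adjusted over the 33 lists, of which about 1 would reach 1 of 35 by chance, so chance is not excluded for any list taken singly.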

Other observations

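All tests in this part were chosen after the results had been seen. They use 9 further gene lists, all written after the table of genes had been examined, with camera p-values adjusted over the 9. None of the 9 passed with an estimated correlation (lowest adjusted p = 0.316), and their counts are descriptions, not independent evidence of a direction.

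Complement genes were lower for 9 of 14 and higher for 2 (camera adjusted p = 0.000954; adjusted p = 0.316 with an estimated correlation). Cfb, factor B of the alternative pathway, changed by -1.44 ± 0.13 (SE) in log2, C4a by -1.08 ± 0.13, C2 by -0.94 ± 0.13 and C3, the central component, by -0.79 ± 0.077, whereas the regulators Cd46 and Cfi were at 0.54 ± 0.089 and 0.42 ± 0.059. C4a and C4b (-0.94 ± 0.097) are near-identical copies whose probes were not compared. Array means of the list differed by -0.453 and did not overlap between the groups. Sirt6 shRNA replicate 2 was at -0.0217 and the other Sirt6 shRNA arrays between -0.319 and -0.279. The same array had the highest microglia marker mean of its group, at 0.325. Reactive astrocyte genes were lower for 9 of 18 and higher for 4 (camera adjusted p = 0.0176; adjusted p = 0.316 with an estimated correlation), with array means apart by -0.263. Serpina3n led the falls, while Hspb1 at 0.93 and S100a10 at 0.41 were among the 4 higher. The list's median of -0.188 was not separated from the fall of astrocyte markers as a whole (median -0.333). Lipoprotein and lipid handling genes were lower for 6 of 15, with Cd36 the 1 that was higher (camera adjusted p = 0.0176; adjusted p = 0.316 with an estimated correlation), but their array means overlapped (difference -0.0207, exact permutation p = 0.6). Circadian clock genes did not pass (4 of 19 higher, 11 lower, camera adjusted p = 0.0588), with Npas2 at -0.61, Dbp at -0.53, Ciart at 0.50 and Per2 at 0.45. Their array means did not overlap, however (difference -0.0889, exact permutation p = 0.0286). Cholinergic genes did not pass either (1 of 8 higher, Slc5a7, camera adjusted p = 0.131), though their array means did not overlap (difference 0.278, exact permutation p = 0.0286).

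The fall of activity-regulated genes was set against fewer neurons and against a short difference in handling at harvest. Fewer neurons would lower presynaptic genes alike, but their median log2 fold change was 0.0825 ± 0.0249 (bootstrap SE) against -0.332 for the activity-regulated list, which argues against that explanation. A difference in handling would spare genes induced over hours. The mean of 10 late-response genes was lower by array, with a difference of -0.152 (exact permutation p = 0.0286), but 1 rose, 4 fell, their median was -0.0802 with a bootstrap SE of 0.16, 5 of them belong to the activity-regulated list, and camera gave an adjusted p of 0.186, so handling stays open. Lower activity of the neurons with less Sirt6, an off-target effect of the shRNA and the slide row, which matches the group, stay open too.

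Fewer astrocytes might account for the fall of astrocyte markers. Of 24 abundant markers, 10 lay over 3 standard errors from their median fall of -0.352, so the markers did not fall by a common amount. Markers that other cells express as well could fall unequally when astrocytes are lost, and this was not tested. The standard errors may also hold technical spread only. The comparison therefore cannot decide whether a lower share of astrocytes is the whole cause. A lower share together with changes of expression within astrocytes, an effect of Sirt6 on these cells and an off-target effect remain untested.

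The rise of contractile genes was described with 34 actin, contractile and serum response factor genes. Of the 29 measured, 19 were higher and 1, Egr1, was lower, with a median of 0.416 (camera adjusted p = 5.33e-06; adjusted p = 0.316 with an estimated correlation). Because these genes were listed after Tagln, Tpm2 and Myl9 had been seen to rise, neither the count nor the p tests whether the pattern holds. Flna was at 0.76 ± 0.053, Vcl at 0.52 ± 0.073 and Srf at 0.42 ± 0.049, while the abundant actins Actb and Actg1 were at -0.11 and -0.032 and were not called. More fibroblasts would raise fibroblast matrix genes by about as much, but their median was 0.0647 ± 0.0786 (17 genes, 6 higher and 1 lower, camera adjusted p = 0.131). Their array means differed by 0.0461 (exact permutation p = 0.4), and by 0.0189 to 0.0759 when 1 array was omitted. Over the 15 that were well above background on all arrays the median was 0.167 ± 0.0767 (array means 0.119 higher, exact permutation p = 0.0286). It lay under the contractile median by barely more than the 2 standard errors asked for (2.01). The highest of the 17, Col1a2 at 0.36, lay under the contractile median. That median rests on genes listed after some had been seen to rise, which may set it too high. Fibroblast and meningeal markers, a list fixed beforehand, had 8 of 24 higher and 5 lower, with a median of 0.0631. Their array means differed by -0.14 without overlap (exact permutation p = 0.0286), so that list did not rise as a whole. Because its members moved both ways, the comparisons cannot decide whether fibroblasts are the whole cause, a smaller share in it or no part of it. For more mural cells, the 9 measured mural genes outside the contractile apparatus had a median of 0.123 ± 0.268 (3 higher and 1 lower, camera adjusted p = 0.371), with Vtn at 0.83, Pdgfrb at -0.074 and Ndufa4l2 at -0.41 (0.097 on its other probe), a spread too wide to decide. Their array means were higher in the Sirt6 shRNA group by 0.272 without overlap (exact permutation p = 0.0286), and by 0.15 without Abcc9, Heyl and Ndufa4l2, which were not well above background on all arrays. The 6 left had a median of 0.102 ± 0.154, which is 1.72 standard errors of the difference under the contractile median where 2 were asked for, so a larger share of mural cells stays open beside a change within cells already present.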
